A study of Caenorhabditis elegans with 14 samples.

How the data were processed

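Expression was measured in whole Caenorhabditis elegans with an Affymetrix array of 22625 probe sets. Per the labels' protocols, embryos were staged, larvae were taken as first-stage larvae (L1), and adults were taken 50 hours past the L4 stage, although the sample titles call them young adults. Total RNA was extracted with Trizol and a column kit, and biotin-labelled cRNA was made from 6 ug of it, per the labels' protocols. The labels put 4 L1 arrays and 3 adult arrays in a daf-19 mutant group, whose genotype is given as daf-19 together with daf-12, and 4 L1 arrays and 3 adult arrays in a control group mutant for daf-12 alone. The contrast therefore compares daf-19 mutants with their controls in a daf-12 mutant background. The labels do not name the daf-19 allele. They call the replicates biological, and nothing in them says which replicates were grown or hybridised on the same day.

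The values are the log2 signals per probe set that the authors deposited for 14 arrays. Background correction, summary method, normalization and software are not given in the sources used here. The unit log2 was read from the deposited values, which carry 2 decimals and span the range usual for log2 array signals. Array medians lay between 4.72 and 4.76 in the deposited log2 values of the 8 L1 arrays and between 5.91 and 6.02 in those of the 6 adult arrays. The quantiles matched within a stage and not between stages, so the stages appear to have been normalized separately. A difference between stages therefore depends on the scaling, whereas a difference between genotypes within a stage does not cross that step.

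The 77 control probe sets were left out, and 22548 were tested. Gene symbols came from a table of the platform's annotation. Of the tested probe sets, 20766 had 1 gene, 887 had several and 895 were not listed in that table and stay unnamed. Gene identifiers were looked up in a RefSeq gene table (assembly WBcel235), which held those of 20701 single-gene probe sets and changed 0 symbols. That table also gave the genes that neighbour daf-19. Names ending in _x_at (1227 probe sets) or _s_at (5484) mark probe sets that can match more than 1 transcript. For gene lists, families and named genes, each of 17118 genes was represented by its probe set with the highest mean over all arrays; 2981 genes had more than 1.

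Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) to the deposited log2 values. One fit with a mean for each of the 4 groups used all 14 arrays, so that the groups shared an estimate of the spread. It had 10 residual and 4.18 prior degrees of freedom. The contrasts were mutant against control at L1, mutant against control in adults, the difference between those effects (adult minus L1, called the interaction), and adult against L1 in each genotype. P-values were two-sided and adjusted by Benjamini-Hochberg over the tested probe sets within each contrast, with a threshold of 0.05. Errors given with fold changes are the standard errors of that fit. The number of arrays limits the precision: the median standard error was 0.11 (log2) at L1 and 0.12 in adults.

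Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 93 tests (31 lists and 3 contrasts), and again with an estimated correlation. The lists covered intraflagellar transport (IFT) particles, IFT motors, the BBSome and small GTPases, the transition zone, other genes listed as X-box or ciliary, sensory transduction, ciliated neuron identity regulators, synapses, transmitter synthesis, FMRFamide-like and other neuropeptides, insulin-like peptides and dauer signalling, transmitter receptors, male-specific ciliated neurons, glia, intestine, yolk, cuticle, moulting, muscle, germline, sperm, early embryo, heat shock, detoxification, immunity, DAF-16 targets, lipid and sugar metabolism, the cell cycle and ribosomal proteins. Some lists shared members, at most 4 between any pair. Families were the 165 sets of at least 10 genes that share a symbol prefix, tested in the same way and adjusted within a contrast. Overlap between the stages was tested with a two-sided Fisher's exact test over the 17118 genes. Chance was judged by refitting other splits of the same arrays, 100 at most for any contrast.

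Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each genotype contrast, the 10 largest rises and falls among genes past the threshold whose mutant arrays all lie on one side of all control arrays. It takes the 5 largest each way for the interaction and, with arrays that do not overlap, the 8 largest each way for each stage contrast. Up to 4 members past the threshold are taken from each list, or the 2 with the smallest p where none passed, and the 2 with the smallest p from each family past the threshold. The genes daf-19 and daf-12 were named in any case. Alternatives were a replicate block, 3 normalizations, a filter on probe sets under the 40th percentile, a floor at the 20th percentile, a trended and robust variance model, fits to the compared groups alone, array weights, leaving out each array, other thresholds, the mean of all probe sets of a gene and an estimated correlation. A block within each stage, a test of the lists with plain _at probe sets alone and a pooled count over the 5 ciliary lists were added after the data were seen. The planned search for X-box motifs in promoters was not run because no genome sequence was used here.

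Replicate numbers were checked for pairing by correlating each mutant array's deviations from its group mean with those of the control array of the same number. The numbers come from the labels. At L1 the correlation lay between 0.19 and 0.42 in all 4 pairs, and between -0.33 and 0.18 in the 12 pairs of unlike number, so the numbers pair the L1 arrays. The adult check is given with the dependence on processing. No 2 arrays held the same values: correlations across probe sets lay between 0.98 and 0.9944 within a group at L1 and between 0.9904 and 0.9974 in adults.

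The pipeline was tested on simulated data drawn from the real means and spreads, with 22548 probe sets. At L1, with 4 arrays each, it recovered 76.1% of probe sets changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold, and 5.9% of its calls were false. In adults, with 3 arrays each, it recovered 56.7%, 88.1% and 98.5%, with 3.0% false calls. A simulated list shifted by -0.3 was called by camera with an adjusted p of 6.91e-17, and 0 of the other lists were. The simulated noise was independent between probe sets and arrays, without correlation between genes and without replicate pairs. The run therefore does not show how often the preset correlation gives false list calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.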

Results

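The data were log2 signals of whole worms on 14 arrays. Of these, 8 came from first-stage larvae (L1), 4 of the daf-19 mutant and 4 of its control, and 6 from adults, 3 of each genotype. The sample titles call these young adults, whereas the protocol gives 50 hours past the L4 stage, and which holds is unknown. Every animal carried a daf-12 mutation, so that the genotypes differed by daf-19 alone as labelled. The gene daf-19 encodes the RFX transcription factor that acts through X-box motifs in the promoters of genes for sensory cilia. The series asks which genes depend on DAF-19 in ciliated and in non-ciliated neurons and at different life stages. Array medians lay between 4.72 and 4.76 at L1 and between 5.91 and 6.02 in adults.

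The transcript of daf-19 itself was lower in the mutants at both stages. The dimmer of its 2 probe sets fell from 6.68 ± 0.20 (SD, n = 4) to 5.99 ± 0.15 at L1, a log2 fold change of -0.69 (SE 0.10, adjusted p = 0.00281). In adults it fell from 7.34 ± 0.09 (SD, n = 3) to 6.70 ± 0.06, by -0.64 (SE 0.12, adjusted p = 0.0163). The brighter probe set fell at L1 (-0.70, SE 0.13, adjusted p = 0.0125) and lay lower by a value that did not pass in adults (-0.56, SE 0.15, adjusted p = 0.105). No mutant array reached the lowest control array of its stage in either probe set. The allele is not named, and where these probes lie relative to the mutation is unknown, so these values check the labels rather than the loss of function. The 3 probe sets of daf-12, mutant in all groups, did not pass at either stage, with L1 values of 0.40, 0.05 and 0.13. The adult call of the dimmer probe set ended without adult mutant array 1 (adjusted p = 0.0776), 2 (0.0734) or 3 (0.0517) or adult control array 3 (0.0848) and after joint quantile normalization (0.184), while the fold change stayed between -0.69 and -0.49 under all alternatives. The call of the brighter one at L1 ended when the adult groups were left out of the fit (adjusted p = 0.105).

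At L1, genes of the sensory cilium were 22 of the 142 genes that fell in the mutants. They lay among 82 distinct genes on 5 ciliary lists, of which 2 rose, and the median log2 fold change over all 82 was -0.19. In the same arrays a measure of RNA quality, the 3' minus 5' signal, was 3.83 to 4.12 in mutants and 3.16 to 3.83 in controls for Gapdh, and 2.83 to 3.06 and 2.44 to 2.88 for actin. The data carry no detection calls; where all arrays of a group lay below their lower quartile of signal, as for C18F10.2, a change to or from that group is written as at least its size. The gene che-3, which encodes the dynein heavy chain of retrograde intraflagellar transport (IFT), fell 3.38-fold, from 7.41 ± 0.02 (SD, n = 4) to 5.66 ± 0.17 (SE of the log2 fold change 0.09, adjusted p = 7.63e-08). Falls also reached ifta-1 and ift-139 of the IFT-A complex (2.46-fold, SE 0.11, adjusted p = 2.32e-05, and a log2 fold change of -1.13, SE 0.10, but 0.12, adjusted p = 0.833, in a dimmer probe set of ift-139), bbs-1 of the BBSome (-1.08), tmem-231 of the transition zone (-1.02) and xbx-9 (-1.52, SE 0.12, adjusted p = 8.18e-06). The gene dyf-11, an IFT-B component, went the other way and rose by 1.20 (SE 0.14, adjusted p = 0.000244), and arl-13, a small GTPase of cilia, rose by 0.86 (adjusted p = 0.00839).

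Within the IFT particle list, 7 of 19 measured genes fell at L1, among them ifta-1, ift-139 and che-2 (-0.80), and 1 rose, dyf-11; adjusted over the list alone, 8 fell and 1 rose. The list's median was -0.23 (camera adjusted p = 4.26e-09; adjusted p = 0.00771 with an estimated correlation, and between 8.42e-10 and 0.0496 over the other alternatives). Of 27 other genes listed as X-box or ciliary, 5 fell, such as xbx-9, xbx-3 (-1.02), asic-2 (-0.90) and ttll-11 (-0.62), and 9 fell adjusted over the list alone. Their median was -0.19 (adjusted p = 1.52e-08; adjusted p = 0.0084 with an estimated correlation). The transition zone list had 5 of 14 genes lower, among them tmem-231, nphp-1 (-0.89) and jbts-14 (at least -0.66; -0.125, adjusted p = 0.772, in a dimmer probe set), or 6 lower and 1 higher adjusted over the list alone. Its median of -0.20 passed (adjusted p = 8.86e-07; -0.12 without L1 mutant array 4) but not at an adjusted p = 0.0602 with an estimated correlation. With dim probe sets left out it turned to 0.16 (adjusted p = 0.34) over the 2 genes that stayed. Both called IFT motor genes of 10 fell, che-3 and the kinesin gene osm-3 (-0.48, adjusted p = 0.0437), whereas 5 fell and 2 rose adjusted over the list alone. The motor list had a median of -0.19 (adjusted p = 0.0106; adjusted p = 0.124 with an estimated correlation, 0.0558 with the replicate pairs as a block, 0.117 without dim probe sets and 0.685 with plain probe sets, against 0.00478 at the least). On the list of the BBSome and small GTPases, bbs-1, bbs-8 (-0.70) and bbs-9 (at least -0.59) fell and arl-13 rose among 12 genes. Adjusted over the list alone, 5 of them fell and 2 rose, and the list as a whole did not pass (median -0.05, adjusted p = 0.0631). It passed without L1 mutant array 2 (-0.155, 0.0288) or L1 control array 2 (0.038), and after joint (0.0463) or per-stage (0.0495) quantile normalization. So it did with a trended, robust variance (0.0379) and with the Gapdh 3' minus 5' signal as a covariate (0.0137). Single arrays decided some of these calls. That of mks-6 (-0.77) ended without L1 control array 4 (adjusted p = 0.0687), and that of asic-2 without L1 mutant array 3 (0.0596) or 4 (0.0511) or L1 control array 3 (0.0551). The call of osm-3 ended without any 1 array other than L1 mutant array 4 or L1 control array 3 (0.0548 to 0.141). With only the L1 groups in the fit, the calls of osm-3, mks-6 and asic-2 ended as well (0.206, 0.123 and 0.129).

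**Figure D1:**
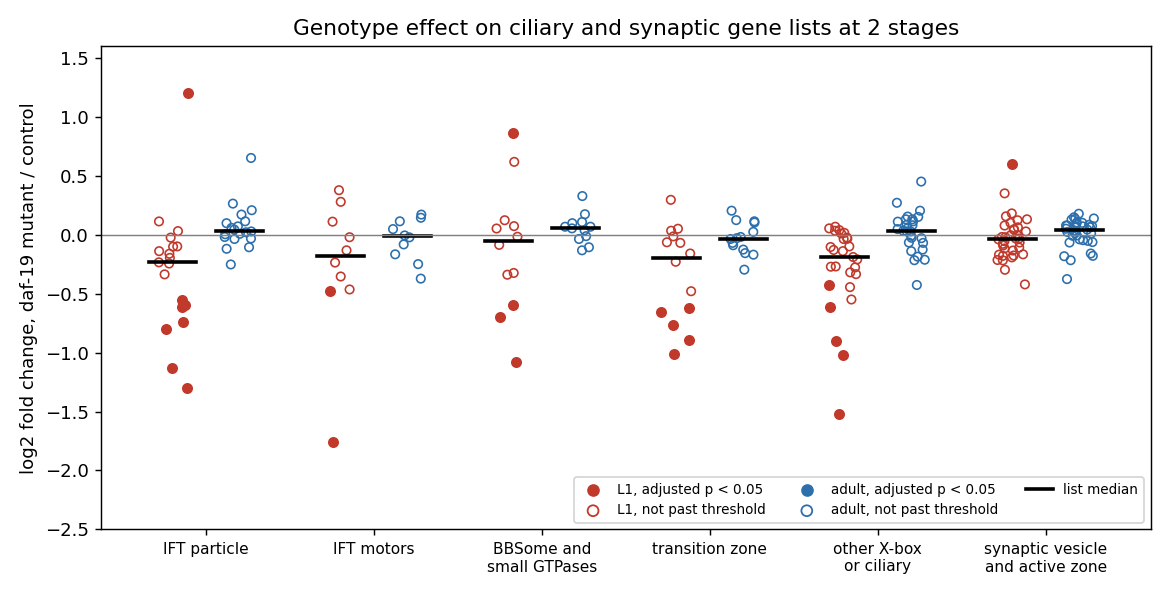
Log2 fold change of each measured gene (mutant minus control) at L1 (red) and in adults (blue) for the 5 ciliary lists and the synaptic list. Filled points have an adjusted p under 0.05 and black bars mark list medians; 22 genes of the ciliary lists fell at L1 and 0 did in adults.

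Cuticle collagens changed in both directions at L1, in arrays whose Gapdh 3' minus 5' signal averaged 3.95 in mutants and 3.62 in controls. The gene col-143 rose from 6.09 ± 0.31 (SD, n = 4) to 9.61 ± 0.43, a log2 fold change of 3.52 (SE 0.19, adjusted p = 9.88e-08), while col-176 fell by 2.41 (SE 0.20, adjusted p = 9.28e-06), col-142 by 2.11 (adjusted p = 0.00672, or 0.0656 with only the L1 groups in the fit) and col-141 by 1.55 (adjusted p = 1.43e-06). Over the 128 measured col genes, 18 fell and 4 rose, with a median of -0.27 (adjusted p = 2.04e-23; adjusted p = 0.693 with an estimated correlation). Without L1 mutant array 3 or L1 control array 2 or 4, 11, 11 or 10 fell. On the epidermis and cuticle list, 1 of 22 genes fell, col-34 (-0.65, adjusted p = 0.0429), and 10 fell adjusted over the list alone. The call of col-34 ended without any L1 array except mutant array 1, and without adult mutant array 2 or 3 or adult control array 2 (0.0557 to 0.141), and after quantile normalization jointly (0.085) or per stage (0.0599). The list's median was -0.30 (adjusted p = 2.14e-08; adjusted p = 0.33 with an estimated correlation).

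Beyond cilia and cuticle, the largest L1 falls included R102.2 (-2.89, SE 0.21, adjusted p = 3.38e-06), Y41E3.5 (-2.88, SE 0.29), the C-type lectin domain gene clec-194 (-2.45, SE 0.13), C18F10.2 (at least -2.37, SE 0.09, adjusted p = 3.82e-09), ddn-2 (at least -2.32, SE 0.15) and ugt-13, a UDP-glucuronosyltransferase gene (-1.99, SE 0.22). The gene cwp-4, of a class named for coexpression with polycystin genes, fell by 1.97 (SE 0.10, adjusted p = 9.88e-08). Rises included nssp-55 (2.22, SE 0.18), the lectin-domain genes clec-10 (2.22, SE 0.31) and clec-31 (2.04, SE 0.31), pho-11 (1.95, SE 0.19, adjusted p = 5.1e-05), C12D5.9 (1.66), the cation ATPase gene catp-2 (1.59), the lysozyme gene ilys-5 (1.46) and the serpentine receptor gene srd-27 (1.46). The rule named these genes only where the 4 mutant arrays lay on 1 side of the 4 control arrays, so that separation is no further evidence. The rise of C23G10.11 by 2.74 (SE 0.57, adjusted p = 0.0304) ended without L1 mutant array 2, 3 or 4, any L1 control array, adult mutant array 3 or adult control array 2 (adjusted p up to 0.0968), and with a trended, robust variance (0.0955). With only the L1 groups in the fit, the calls of clec-31 (0.0654), C12D5.9 (0.061), catp-2 (0.104) and srd-27 (0.104) ended.

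On lists of neuronal genes other than those of cilia, at most 1 gene each was called at L1. Over all genes 208 of 17118 were called, so these counts do not show that neuronal genes were spared. On the synaptic vesicle and active zone list, 1 of 35 genes passed: dyn-1, which encodes dynamin, rose by 0.60 (SE 0.12, adjusted p = 0.0192; 0.09, adjusted p = 0.936, in a dimmer probe set), and the list did not pass (median -0.03, adjusted p = 0.78). That call ended without L1 mutant array 3 (adjusted p = 0.0619) or L1 control array 4 (0.0559). Among other neuropeptides, nlp-2 rose by 0.53 (adjusted p = 0.0187; 0.0632 without L1 control array 2 and 0.0683 without 4), and among insulin-like peptides and dauer signalling, ins-22 fell by 0.55 (adjusted p = 0.0492). The call of ins-22 ended with either replicate block (0.0828 and 0.0592) and without any 1 array other than adult control array 1 or 3 (0.0527 to 0.126). With only the L1 groups in the fit those of dyn-1 (0.134) and nlp-2 (0.0606) ended, as did that of nlp-2 with array weights (0.0552). These lists gave adjusted p = 0.176 and 0.98. Other neuropeptides passed without L1 control array 4 (0.0413), and FMRFamide-like peptides without L1 control array 2 (0.0442). With the Gapdh 3' minus 5' signal as a covariate, a fit chosen after the data were seen, FMRFamide-like peptides also passed as lower (median -0.158, camera adjusted p = 0.000584). Adjusted over the list alone, dyn-1 and nlp-2 were again the 1 gene called, and 2 genes fell and 2 rose on the insulin list. Of 11 genes of male-specific ciliated neurons, cwp-4 alone fell, 1 fell adjusted over the list alone, and the list gave an adjusted p = 0.111 (0.0485 with the Gapdh covariate). The lists of sensory transduction (adjusted p = 0.383), ciliated neuron identity regulators (0.853), transmitter synthesis (0.853), FMRFamide-like peptides (0.383), transmitter receptors (0.479) and glia (0.638) held 0 genes called by the probe set that represents them. Dimmer probe sets were called for tax-4 of sensory transduction, which rose (0.84, adjusted p = 9.52e-05), and for eat-4 of transmitter synthesis, which fell (-0.62, adjusted p = 0.0276).

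Of the remaining lists, detoxification had 2 of 38 genes lower at L1, cyp-35B1 (-1.67, adjusted p = 0.0432) and sod-1 (-0.44, adjusted p = 0.0332), with a median of -0.17 (adjusted p = 0.0106; adjusted p = 0.63 with an estimated correlation). The intestinal gene cpr-6 rose by 1.15 (adjusted p = 0.000231), the immunity gene ilys-3 by 1.11 (adjusted p = 0.0179; 0.0551 without L1 control array 4) and the sperm gene spe-4 by 0.53 (adjusted p = 0.0206), and hsp-4 of the unfolded protein response fell by 1.07 (adjusted p = 0.022). Their lists did not pass (adjusted p = 0.944, 0.942, 0.428 and 0.824), although with the Gapdh covariate the heat shock list passed as higher (median 0.164, adjusted p = 0.0261). The call of spe-4 ended without L1 mutant array 3 (0.0602) or 4 (0.0511) or L1 control array 3 (0.0673), and that of hsp-4 without L1 mutant array 2 (0.0602) or 3 (0.0795) or L1 control array 3 (0.0638). The gene cyp-35B1 lost its call without L1 mutant array 2 or 3, L1 control array 1 or 4 or any adult array (0.0523 to 0.136). For sod-1 it ended with either replicate block (0.0508 and 0.0538) and without L1 mutant array 3 or 4, L1 control array 1, 3 or 4, adult mutant array 1 or 2 or adult control array 2 (0.0517 to 0.114). The detoxification list lost its call without L1 mutant array 3 (median -0.07, adjusted p = 0.249) or L1 control array 4 (-0.10, 0.0792). With only the L1 groups in the fit, the calls of spe-4 (0.121), hsp-4 (0.156), cyp-35B1 (0.212), sod-1 (0.153) and ilys-3 (0.134) ended, and that of cyp-35B1 also with a trended, robust variance (0.0916). The oocyte and germline list (median 0.06, adjusted p = 0.0059) and the cell cycle list (0.05, adjusted p = 0.0157) passed with 0 called genes, each at an adjusted p = 0.783 with an estimated correlation, and rested on single arrays. Without L1 mutant array 2 or 3 or L1 control array 1, the germline call ended (adjusted p = 0.0658, 0.0633 and 0.144, with a median of 0.04 without mutant array 3), and so did the cell cycle call (0.192, 0.285 and 0.149, with medians of 0.02, 0.03 and 0.06). Without L1 mutant array 1 or 4 or L1 control array 3 both stayed called, at medians of 0.10, 0.10 and 0.09 for germline and 0.12, 0.11 and 0.08 for cell cycle genes. The lists of yolk proteins (adjusted p = 0.84), moulting (0.983), muscle (0.725), early embryo (0.831), DAF-16 targets (0.931), lipids (0.846), sugars (0.782) and ribosomal proteins (0.332) did not pass and held 0 genes called by limma in the probe set that represents them. Ribosomal proteins passed without L1 mutant array 1 (0.03, 0.0393). Dimmer probe sets of the muscle gene unc-60 (0.49, adjusted p = 0.0317) and of mtl-2, on the intestine and detoxification lists (0.545, adjusted p = 0.0467), were higher. Adjusted over the list alone, 3 detoxification genes fell, 1 intestinal gene rose and 2 fell, 2 immunity genes rose and 1 fell, 1 heat shock gene each way and 1 sperm and 1 germline gene rose, and 4 lipid genes each way passed (8 higher and 5 lower at unadjusted p). Over the 14 lists with 0 called genes by either adjustment, limma gave 19 higher and 10 lower at unadjusted p among 399 genes. Families past the threshold besides col were pals (median -0.39, 2 of 23 lower, adjusted p = 3.12e-07), che (0.00332), osm (0.0281) and gst (0.041), which lay lower, and gcy (0.041) and srd (0.0451), which lay higher; none of them passed with an estimated correlation. Of the pals calls, that of pals-33 ended without L1 control array 2 (0.0534) or 4 (0.0559). That of pals-29 ended with either replicate block (0.068) and without any 1 array other than L1 mutant array 1 or L1 control array 1 (0.0552 to 0.144), and both ended with only the L1 groups in the fit (0.129 and 0.228). L1 control array 1 lay with the mutants in the median deviation of pals genes, at -0.18 against -0.24 to -0.09 in mutants and 0.09, 0.11 and 0.38 in control arrays 2, 3 and 4. Without it 8 pals genes were lower, and without control array 2 or 4 none was, at family medians of -0.25 and -0.23 that still passed. Without L1 mutant array 2, 3 or 4 or L1 control array 3, 1 pals gene was lower. The other small families rested on single arrays. The gst call ended without L1 mutant array 3 (-0.10, 0.595) or L1 control array 2 (0.126) or 4 (-0.10, 0.606), and that of osm without L1 mutant array 1 (0.112) or L1 control array 2 (0.0771) or 4 (0.0911). The gcy call ended without L1 mutant array 3 (0.152) or 4 (0.0994) or L1 control array 2 (0.179). That of srd ended without L1 mutant array 1 (0.174), 2 (0.0919) or 3 (0.0568) or L1 control array 2 (0.0771) or 3 (0.212). The che family kept its call, at a median of -0.17 against -0.11 without L1 mutant array 1. The called che genes (che-2, che-3 and che-11) and osm genes (osm-1, osm-3 and osm-5) were ciliary genes already counted above, so these families are not separate findings.

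In total, 257 of 22548 probe sets changed at L1, 79 higher and 178 lower, for 66 genes that rose and 142 that fell. The median size of the called changes was 0.79. Of 58 named genes called at L1, 23 lost the call with only the L1 groups in the fit. Replicate numbers paired the L1 arrays, and a block for those pairs raised the count to 525, whereas fitting the L1 groups alone lowered it to 98 and leaving out L1 control array 4 to 153.

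In adults, no ciliary gene changed past the threshold. By limma 0 of the 82 genes passed, with 3 higher and 3 lower at unadjusted p, and the median was 0.03. The 22 genes lower at L1 had a median log2 fold change of -0.05 in adults against -0.76 at L1, a value inflated because the genes were chosen for that fall. Signal of che-3 in adults was 6.49 ± 0.06 (SD, n = 3) in controls and 6.41 ± 0.12 in mutants. No ciliary list passed in adults: the IFT particle gave an adjusted p = 0.528, IFT motors 0.773, the BBSome 0.78, the transition zone 0.527 and other ciliary genes 0.824. The smallest p values among these genes belonged to dyf-11 (0.65, adjusted p = 0.0784), the 1 gene higher adjusted over the list alone, to wdr-31 (0.27, adjusted p = 0.193) and to xbx-9 (-0.43, adjusted p = 0.265). Control signals of the 22 genes ranked at a median percentile of 56.0 at L1 and 28.2 in adults. For 7 of them, ifta-2, che-11, bbs-9, tmem-231, nphp-1, jbts-14 and ttll-11, both adult groups lay below the lower quartile. A fall may have been hard to see there, although that quartile is not a limit of detection.

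The genes called in adults lay outside the ciliary lists, and their functions were not tested. The gene rnh-1.3, which encodes an RNase H, rose from 8.25 ± 0.03 (SD, n = 3) to 11.51 ± 0.22, a log2 fold change of 3.26 (SE 0.14, adjusted p = 1.23e-08). Other rises were in far-3, a fatty acid and retinol binding protein gene (2.60, SE 0.26), F49E11.2 (2.34, SE 0.11, adjusted p = 1.43e-08), clec-61 (2.06, SE 0.33), F59A7.2 (1.91, SE 0.14), the acid sphingomyelinase gene asm-3 (1.59) and gst-20, a glutathione S-transferase gene (1.59, SE 0.17, adjusted p = 0.000217). The largest fall was in T22B7.7, from 9.78 ± 0.64 to 4.65 ± 0.29 (-5.12, SE 0.23, adjusted p = 1.23e-08). Other falls were in K07C11.7 (-1.97, SE 0.18), Y51H7C.1 (-1.88, SE 0.19), Y41E3.5 (-2.09, SE 0.33, adjusted p = 0.0052) and Y38E10A.14 (-1.82; adjusted p = 0.00817, or 0.0511 without adult mutant array 1). The rise of B0024.4 by 2.27 (adjusted p = 0.0104) ended without adult control array 2 (0.0687) or 3 (0.0623). With only the adult groups in the fit, the calls of B0024.4 (0.132), clec-61 (0.0985) and Y41E3.5 (0.0643) ended.

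Innate immunity genes went both ways in adults. The infection response gene irg-5 fell from 10.57 ± 0.25 (SD, n = 3) to 7.23 ± 0.20 (-3.34, SE 0.15, adjusted p = 1.23e-08), dod-24 from 10.37 ± 0.80 to 6.75 ± 0.63 (-3.62, SE 0.43, adjusted p = 0.000547) and dod-22 by 1.53 (adjusted p = 0.000145), whereas cnc-4 rose by 1.12 (adjusted p = 0.0429, lost without L1 control array 1, 2 or 4, any adult mutant array or adult control array 2 or 3, at 0.0516 to 0.212). Over the 41 genes, 3 fell and 2 rose, or 4 and 3 adjusted over the list alone, and the list did not pass (median 0.04, mean -0.16, adjusted p = 0.327). Of 25 DAF-16 target genes, dod-24 and dod-22 fell; adjusted over the list alone, 2 fell and 6 rose, and the list did not pass (adjusted p = 0.484).

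Genes of the early embryo and families of F-box and Skp1-related genes lay lower in adult mutants. Of 23 early embryo genes, 4 fell, among them sdz-28 (-1.57, adjusted p = 0.0102), vet-6 (-1.34, adjusted p = 0.00136) and pes-10 (-1.04, adjusted p = 0.000555), and 1 rose, sdz-24 (1.78, SE 0.24, adjusted p = 0.00144); adjusted over the list alone, 7 fell and 1 rose. The list's median was -0.05 and its mean -0.20 (adjusted p = 0.000644; adjusted p = 0.124 with an estimated correlation). Without adult mutant array 3 or adult control array 1 or 3 the median was -0.08, -0.09 or -0.09. The fbxb family had 8 of 95 genes lower and a median of -0.21 (adjusted p = 7.93e-21; adjusted p = 0.0861 with an estimated correlation), with fbxb-42 at -0.44 and fbxb-85 at least at -0.47. The number of fbxb genes lower was 0, 2 or 1 without adult mutant array 1, 2 or 3 and 20, 0 or 2 without adult control array 1, 2 or 3, while the family stayed past the threshold without each of them. The skr family had 4 of 19 genes lower, such as skr-7 (-0.98, SE 0.11, adjusted p = 0.000217) and skr-10 (-0.77, adjusted p = 0.00259), and a median of -0.23 (adjusted p = 4.38e-08; adjusted p = 0.0861 with an estimated correlation). Other families that lay lower were sdz (5 of 32 lower and 1 higher, adjusted p = 0.00114; sdz-30 fell by 1.23), fbxc (0.0166), mig (2.66e-05), ceh (0.0488), dpy (0.000286) and col (median -0.14, adjusted p = 4.18e-14); none of them passed with an estimated correlation. By limma 0 of the 128 col genes passed in adults in the probe set that represents them, with 0 higher and 32 lower at unadjusted p, while a dimmer probe set of col-119 was lower (-0.93, adjusted p = 0.0285). Without adult control array 1, 7 skr and 19 col genes were lower, and without adult control array 3 the skr median was -0.13. The sdz count was 3 without adult mutant array 1 or 3 and 2 without adult control array 2 or 3. The calls of sdz-28, fbxb-42 and fbxb-85 each ended without adult control array 2 or 3 (adjusted p = 0.0669 and 0.0612 for sdz-28), those of fbxb-42 and fbxb-85 also without adult mutant array 1 or 2, and that of fbxb-85 also without adult mutant array 3, at an adjusted p of at most 0.0892. With only the adult groups in the fit, those of sdz-28 (0.129), vet-6 (0.0538) and fbxb-42 (0.0562) ended, and after joint quantile normalization those of fbxb-42 (0.0722) and fbxb-85 (0.0802).

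**Figure D2:**
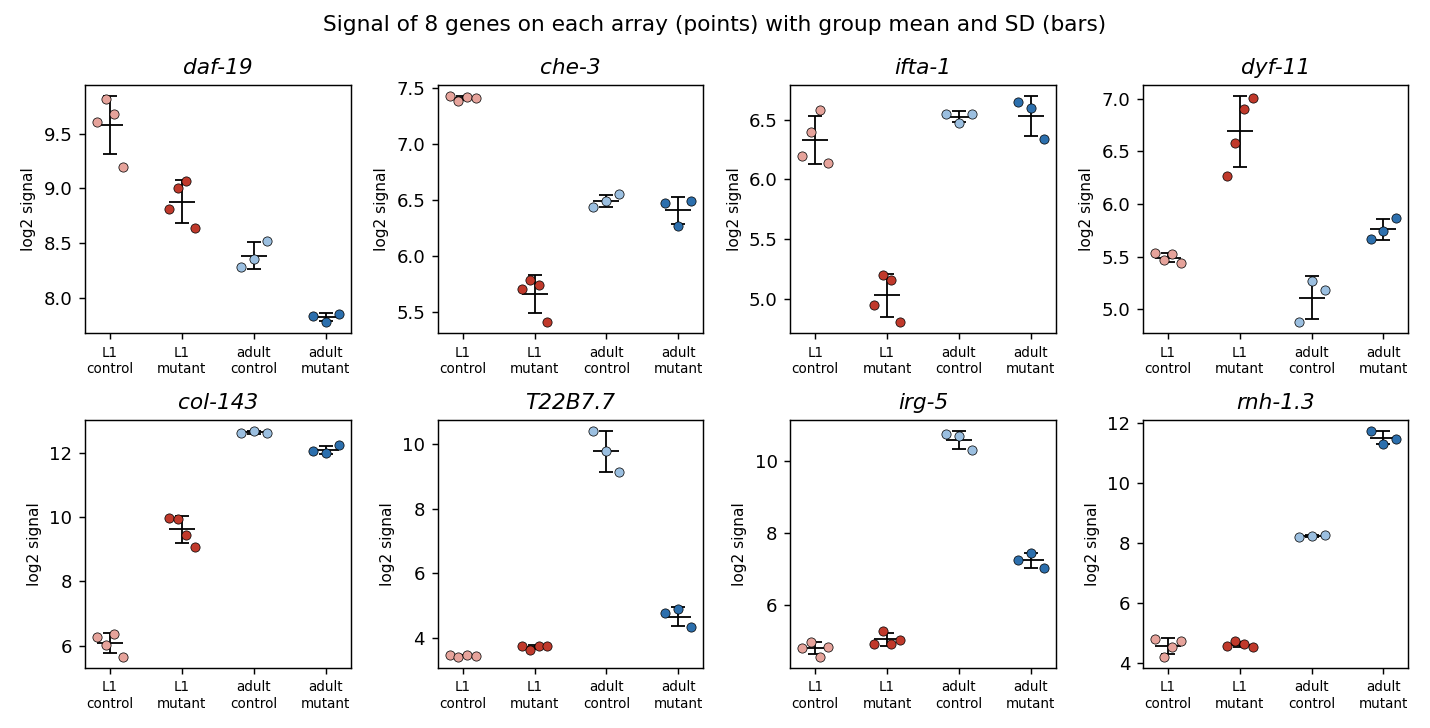
Log2 signal of 8 genes in each of the 14 arrays, grouped by stage and genotype, with the mean and SD of each group (n = 4 at L1, n = 3 in adults). The gene che-3 fell at L1 and had no call in adults, and T22B7.7, irg-5 and rnh-1.3 changed in adults.

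Cuticle, moulting and muscle lists also lay lower in adult mutants. The epidermis and cuticle list had a median of -0.36 (adjusted p = 7.49e-10; adjusted p = 0.249 with an estimated correlation) with 0 of 22 genes called by limma and 9 lower adjusted over the list alone. Moulting genes had a median of -0.25 (adjusted p = 0.000185; adjusted p = 0.72 with an estimated correlation), although the 1 called gene of 28, grd-3, rose (0.77, adjusted p = 0.0268), as it did adjusted over the list alone. Muscle genes had a median of -0.07 with tni-3 lower (-0.98, adjusted p = 0.0156; list adjusted p = 0.00686, or 0.783 with an estimated correlation). In the cuticle list, adult control array 1 lay with the mutants: its median deviation from the adult mean was -0.16, against -0.33 to -0.08 in mutants and 0.30 and 0.37 in control arrays 2 and 3. For moulting genes it stood apart from both groups, at -0.32 against -0.13 to -0.08 in mutants and 0.22 and 0.34 in those controls. The moulting median was -0.45 without adult control array 1, its call ended without adult control array 3 (-0.09, adjusted p = 0.103), and the muscle call ended without that array (0.005, 0.423) or adult mutant array 1 (-0.01, 0.383). The muscle median was -0.145, -0.13 or -0.13 without adult mutant array 2 or 3 or adult control array 1. The call of grd-3 ended without adult mutant array 2 or 3 or adult control array 2 or 3 (up to 0.165), and that of tni-3 without adult control array 2 (0.0886) or 3 (0.0795) or with only the adult groups in the fit (0.107).

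Neuronal and other lists gave 0 called genes in adults by limma in the probe sets that represent them; a dimmer probe set of the intestinal gene asp-5 was lower (-0.37, adjusted p = 0.02). The synaptic list had a median of 0.04 (adjusted p = 0.964), and sensory transduction (adjusted p = 0.558), transmitter synthesis (0.528), FMRFamide-like peptides (0.599), other neuropeptides (0.628), insulin-like peptides and dauer signalling (0.792), transmitter receptors (0.346) and male-specific ciliated neurons (0.599) did not pass. Without adult control array 1, FMRFamide-like peptides (-0.13, 0.00533) and other neuropeptides (-0.125, 0.0491) passed as lower, and without adult control array 3 other neuropeptides passed as higher (0.18, 0.00294). The ciliated neuron identity regulators (median -0.08, adjusted p = 0.0194; 0.783 with an estimated correlation), glia (-0.06, 0.0327; 0.633) and oocyte and germline genes (0.09, 0.0283; 0.815) passed as lists only. Each rested on single arrays. The identity list lost its call without adult mutant array 3 (0.0836) or adult control array 2 (0.177) or 3 (median -0.04, 0.148), and its median was -0.12 without adult mutant array 1 and -0.16 without adult control array 1. Glia lost it without adult mutant array 1 (0.103) or adult control array 2 (-0.04, 0.369) or 3 (-0.10, 0.114), at medians of -0.11, -0.09 and -0.12 without adult mutant array 2 or 3 or adult control array 1. Germline genes lost it without adult mutant array 1 (0.129) or 3 (0.0979) or adult control array 2 (0.143) or 3 (0.04, 0.555), with a median of 0.16 without adult control array 1. The lists of intestine (0.0944), yolk proteins (0.528), sperm (0.529), heat shock (0.846), detoxification (0.0944), lipids (0.599), sugars (0.219), cell cycle (0.529) and ribosomal proteins (0.782) did not pass. Of these, intestine passed without adult control array 1 (0.0267), detoxification without adult mutant array 1 (0.034) or 2 (0.0443) or adult control array 2 (0.0214), and sugars without adult mutant array 1 (0.0179) or adult control array 3 (0.0152). Adjusted over the list alone, 6 detoxification genes were higher and 1 lower, 2 intestinal genes passed each way and 1 sugar metabolism gene was higher. Over the 21 lists with 0 called genes by either adjustment, ciliary ones included, limma gave 16 higher and 24 lower at unadjusted p among 558 genes.

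In total, 71 probe sets rose and 160 fell in adults, for 182 genes of which 63 rose, with a median size of 0.86. Of 37 named genes called in adults, 13 lost the call with only the adult groups in the fit. Leaving out adult control array 1, which lay among the mutants on the first principal component, raised the count to 765; without adult mutant array 1, 2 or 3 or adult control array 2 or 3 it was 121, 144, 120, 103 or 112.

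Whether the effect of daf-19 differed between the stages was tested as the interaction, adult minus L1. The largest differences upward were rnh-1.3 (3.22, adjusted p = 2.77e-07), ugt-13 (2.88, adjusted p = 0.000699), far-3 (2.72), col-142 (2.53, adjusted p = 0.0374) and C18F10.2 (at least 2.40). The call of col-142 ended without any 1 array other than L1 mutant array 1, L1 control array 2 or adult control array 1 (0.0527 to 0.117), after joint quantile normalization (0.0539) and with a trended, robust variance (0.0657). Downward, the largest were T22B7.7 (at least -5.39, adjusted p = 2.77e-07), dod-24 (-4.82), col-143 (-4.06, adjusted p = 2.94e-06), irg-5 (-3.59) and clec-10 (-3.21). The 22 ciliary genes that fell at L1 were chosen for that fall in the same arrays, which favours a difference. Of them, 10 passed this test and 12 did not, such as che-11 (adjusted p = 0.618), nphp-4 (0.409) and mks-6 (0.378). Those of che-3 (1.67), ifta-1 (1.31), bbs-1 (1.18), xbx-9, ift-139 and xbx-3 (0.95) held without each array in turn, and those of che-2, jbts-14, ttll-11 and osm-5 did not (adjusted p up to 0.102, 0.0937, 0.132 and 0.0841). Adult mutant array 1 or 2 or adult control array 2 was enough to end each of these 4. So was adult mutant array 3 or L1 control array 2 for all but ttll-11, and L1 mutant array 3 for all but osm-5. L1 mutant array 4 and L1 control array 4 ended che-2 and ttll-11, L1 mutant array 2 and L1 control array 3 ended jbts-14 and ttll-11, and L1 mutant array 1 and adult control array 3 ended ttll-11. As lists, the IFT particle (median 0.36, adjusted p = 4.38e-07; 4 of 19 genes, or 6 adjusted over the list alone; adjusted p = 0.0084 with an estimated correlation) and other ciliary genes (0.20, adjusted p = 2.99e-06; 3 of 27, or 8 adjusted over the list alone; 0.0177) differed between the stages. The transition zone passed only with the preset correlation (0.20, adjusted p = 0.00108; 0.35 without L1 mutant array 1; 0.219 with an estimated correlation), and IFT motors (0.17, adjusted p = 0.075) and the BBSome (0.04, adjusted p = 0.0786) did not pass. Without L1 mutant array 4 the motors passed (0.0417), and without L1 mutant array 2 (0.16, 0.0408) or L1 control array 2 (0.0442) the BBSome did. Detoxification lay higher (0.25, adjusted p = 0.0049, 3 of 38 genes higher) and so did male-specific genes (0.15, adjusted p = 0.0466), while early embryo (-0.09, adjusted p = 0.0049), moulting (-0.29, 0.0092), muscle (-0.14, 0.0204) and cell cycle genes (-0.11, 0.0211) lay lower, none of these with an estimated correlation. Of these calls, that of male-specific genes ended with either replicate block (0.0735 and 0.124) and without L1 mutant array 1 (0.0534) or 4 (0.181), L1 control array 1 (0.0924) or 4 (0.0695), adult mutant array 2 (0.09, 0.156) or adult control array 1 (0.143). Moulting ended without adult control array 2 (-0.14, 0.113) or 3 (-0.14, 0.221) and had a median of -0.44 without 1. Muscle ended without L1 mutant array 3 (0.0577), L1 control array 4 (0.106), adult mutant array 1 (-0.02, 0.303) or adult control array 3 (-0.04, 0.374), at -0.23 without adult control array 1. The cell cycle ended without L1 mutant array 2 (-0.06, 0.108) or 3 (-0.07, 0.17), L1 control array 1 (-0.04, 0.103), adult mutant array 2 (0.111) or adult control array 1 (-0.05, 0.208), at -0.18 without L1 mutant array 1. Calls kept were detoxification at 0.15 without L1 mutant array 3 (0.0494) and the early embryo. The early embryo median was -0.17, -0.04, -0.05 or -0.18 without L1 mutant array 1, 2, 3 or 4, -0.06 without L1 control array 3 and -0.045 or -0.17 without adult control array 2 or 3. The families gst (0.27), pals (0.40) and osm (0.30) differed upward and fbxb (-0.17), skr (-0.41), mig (-0.23), let (-0.17) and sdz (-0.10) downward, none with an estimated correlation. For skr-7, skr-10, fbxb-42, fbxb-85, sdz-30 and pes-10 both L1 groups lay below the lower quartile. An L1 fall may have been hard to see there, so the difference may only restate the adult fall. Lists that passed only with changes to the arrays used were cuticle (0.00078) and other neuropeptides (0.00884) without adult control array 1, and the identity regulators without that array (0.001), L1 mutant array 1 (0.026) or 4 (0.0496) or L1 control array 2 (0.0442). Glia passed with either replicate block (0.0205 and 0.0247) and without L1 mutant array 1 (0.026) or 4 (0.0496), L1 control array 2 (0.0442) or 3 (0.037) or adult control array 1 (0.00449). The synaptic list did not differ (adjusted p = 0.84). Over the 3 genotype contrasts, 24 of 93 list tests passed with the preset correlation and 4 with an estimated one: the IFT particle and other ciliary genes, each at L1 and in the interaction. In total, 206 probe sets passed the interaction, 105 higher and 101 lower. Without adult control array 1 the count was 562, and without adult mutant array 1, 2 or 3, adult control array 2 or 3 it was 131, 128, 122, 91 or 128.

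Few genes changed at both stages. Genes lower at both numbered 4 where 0.99 were expected if calls were independent (Fisher's exact test, two-sided, p = 0.0173): Y41E3.5, R102.2, clip-1 and gakh-1. Genes higher at both numbered 3 where 0.24 were expected (Fisher's exact p = 0.00184): gst-20, F44G4.7 and tag-123. A further 3, srp-3, glb-1 and F44A2.3, fell at L1 and rose in adults. Both contrasts shared 1 estimate of spread per probe set, so a small estimate favours a call at both stages. The Fisher p-values do not allow for that and do not show a dependence on daf-19 at both stages. Apart from those that the rule named, these genes were chosen after their values were seen. For example, Y41E3.5 had log2 fold changes of -2.88 at L1 and -2.09 in adults, and gakh-1 of -0.57 and -0.60. Across all genes, which are not independent replicates, fold changes at the stages had a correlation of r = -0.003. The count of genes lower at both was 13 without adult control array 1, 22 with array weights and 0 with only the compared groups in the fit.

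Between L1 and adulthood, most of the transcriptome differed in both genotypes, and the median probe set shifted by 0.90 in controls and 0.91 in mutants, a shift that depends on how the stages were scaled. The measure of RNA quality moved with stage: the 3' minus 5' signal of Gapdh was 3.16 to 4.12 at L1 and -0.54 to -0.36 in adults, and that of actin 2.44 to 3.06 and 0.18 to 0.28. Differences between the stages were not told apart from RNA quality. Relative to that shift, the yolk protein gene vit-2 was higher in adult controls by at least 9.01 (from 3.18 to 13.10 in signal, n = 4 and 3), ule-4, named for expression in the uterine lumen, by at least 9.24, and the eggshell proteoglycan gene cpg-2 by 8.74. The genes vit-5, vit-4, vit-1, D1054.10, whose L1 controls also lay below the lower quartile, and ZK813.1 were the others of the 8 named rises, and the same 8 genes were named in mutants. At L1 vit-2 and ule-4 lay below each array's lower quartile (3.71 to 3.76), so their sizes are lower bounds, and the order of the 8 is uncertain. Relative to the shift, dbd-13 was lower in adult controls by a log2 fold change of -8.03, clik-2 by -7.43 and spp-12 by -7.10. In mutants, the pharyngeal myosin gene myo-1 (-6.74) and unc-22, which encodes twitchin (-6.58), were among the largest falls. All 16 named genes of each genotype stayed past the threshold under every alternative run. By limma 20312 probe sets passed in controls, 83.4% of them higher in adults, and 20300 in mutants, 83.6% higher. When all arrays were quantile normalized together, 16922 and 16919 passed and 48.7% and 48.5% of them were higher, so the balance of rises and falls rested on the scaling; 3164 and 3248 probe sets passed both ways in opposite directions.

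**Figure D3:**
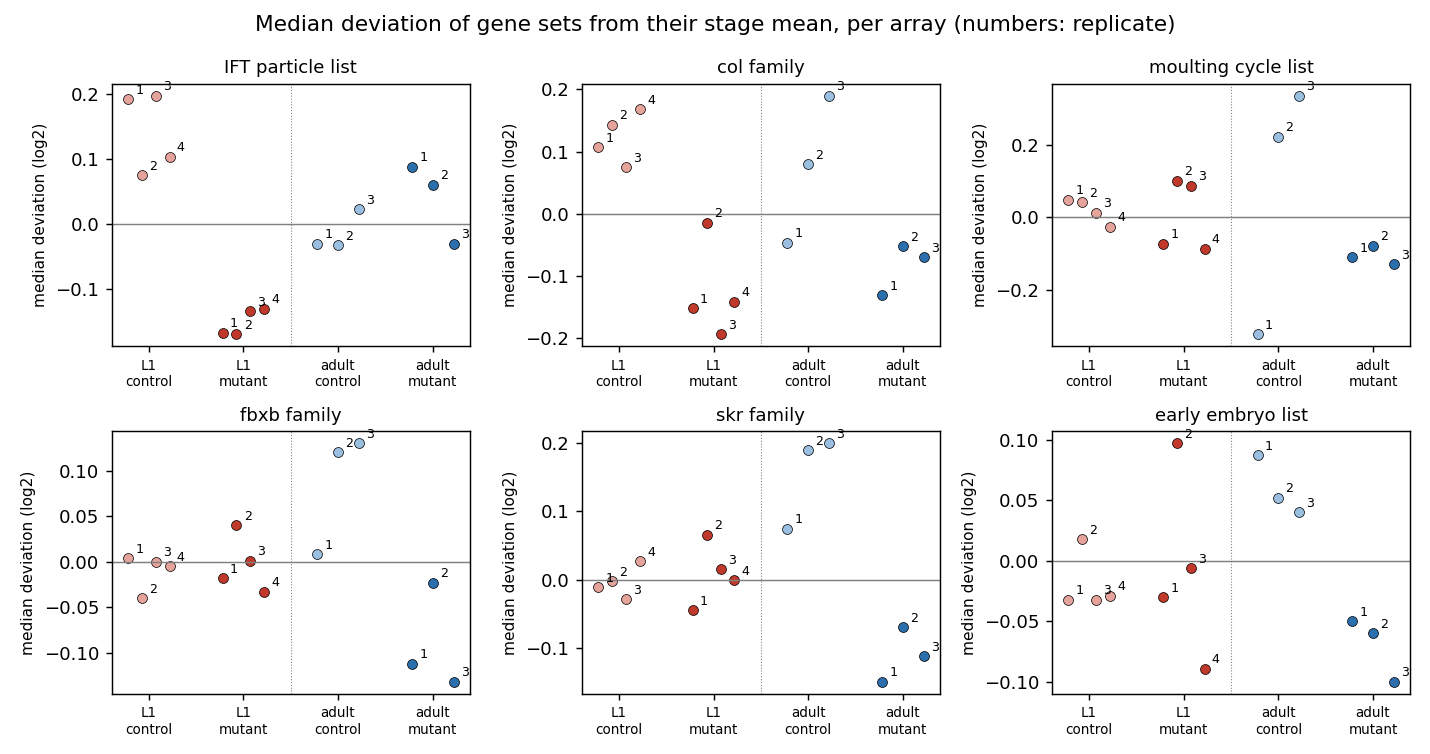
Median deviation of 6 gene sets from their stage mean in each array, on the log2 scale, with points numbered by replicate and grouped by stage and genotype. For moulting genes adult control array 1 (-0.32) lies below the mutants (-0.13 to -0.08) and apart from control arrays 2 and 3 (0.22 and 0.34).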

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

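The tests of adult signal near background, of mislabelled adult arrays, of single arrays, of the share of embryos, of RNA quality at L1, of the spread between collagen scores, free, within pairs or against all families, and of the moulting phase were chosen only after the result each concerns had been seen; the others were planned.

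Of 396 groups of 4 arrays tested, 18 held 1 array far from the other 3 by Dixon's criterion, against about 19.8 by chance, since chance picks about 1 in 20 groups. Only L1 groups hold 4 arrays, so the adult groups were not tested. Among mutants, C23G10.11 had 5.02 in array 1, nssp-55 8.58 in array 2, T22B7.7 3.63 in array 2, dod-24 7.25 in array 1, mks-6 3.42 in array 2, asic-2 5.54 in array 1, pes-1 4.28 in array 1, wdr-31 3.81 in array 3, str-2 3.84 in array 2 and col-119 11.86 in array 1. Among controls, K07C11.7 had 10.63 in array 1, flp-19 11.97 in array 4, ins-6 3.76 in array 3, cpg-1 6.55 in array 1, pdi-2 8.14 in array 2, gst-5 9.69 in array 1, rpl-11.2 13.29 in array 2 and ceh-43 4.87 in array 2.

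Many named genes had an effect of daf-19 that differed between the stages by the interaction test (adult minus L1, limma). They were named mainly for a change at 1 stage or for this difference itself, in the same arrays. That choice favours a difference of matching sign, so their number is no further evidence. Among ciliary genes the differences were 1.67 for che-3, 1.31 for ifta-1, 1.03 for ift-139, 0.83 for che-2, 0.72 for osm-5, 1.18 for bbs-1, 0.59 for jbts-14, 1.1 for xbx-9, 0.95 for xbx-3 and 0.74 for ttll-11. Genes with a fall at L1 and a positive difference were R102.2 (1.55), clec-194 (2.34), col-176 (2.28), C18F10.2 (at least 2.40), ddn-2 (at least 2.34), col-142 (2.53), ugt-13 (2.88), cwp-4 (1.86), col-141 (1.3), ins-22 (0.93) and sod-1 (0.76). Genes with a rise at L1 and a negative difference were col-143 (-4.06), nssp-55 (-2.46), clec-10 (-3.21), clec-31 (-2.36), pho-11 (-1.53), C12D5.9 (-2.39) and cpr-6 (-1.3). Genes with a rise in adults and a positive difference were rnh-1.3 (3.22), far-3 (2.72), F49E11.2 (2.23), clec-61 (2.37), F59A7.2 (2.12), sdz-24 (2.03), grd-3 (1.00) and cnc-4 (1.57). Falls in adults went with negative differences in T22B7.7 (at least -5.39), dod-24 (-4.82), irg-5 (-3.59), dod-22 (-1.77), K07C11.7 (-1.95), Y51H7C.1 (-1.77), Y38E10A.14 (-1.88), tni-3 (-1.13), vet-6 (-1.34), pes-10 (-1.15), sdz-30 (-1.25), skr-7 (-0.97), skr-10 (-0.83), fbxb-42 (-0.49) and fbxb-85 (-0.52). The genes gst-5 (1.45) and fat-5 (1.42) differed without a call in adults. At L1 pes-10, sdz-30, skr-7, skr-10, fbxb-42 and fbxb-85 lay below the lower quartile in both genotypes, and in adults clec-194, ddn-2, jbts-14 and ttll-11 did. For these genes the difference may only restate the change at the other stage. Of these 53 differences, 31 stayed past the threshold with each array left out in turn. The other 22 all ended without adult control array 2, and vet-6 and skr-10 without it alone (0.0577 for both). Those that ended without few other arrays were pho-11 (adult mutant array 2 or 3 or adult control array 3, up to 0.0629), C12D5.9 (adult mutant array 1 or adult control array 3, up to 0.0659) and clec-61 (adult mutant array 2 or 3, up to 0.0629). So did sod-1 (adult mutant array 3 or adult control array 3, up to 0.0752) and osm-5 (L1 control array 2 or any adult mutant array, up to 0.0841). The rest ended without most arrays, and stayed only as follows. Without L1 mutant array 1, the differences that stayed were clec-31, R102.2, col-142, che-2, jbts-14, ins-22, grd-3, gst-5, cnc-4 and fat-5; without 2, clec-31, R102.2, che-2, grd-3, tni-3, fat-5 and fbxb-42; without 3, cnc-4, fat-5 and fbxb-85; without 4, clec-31, jbts-14, grd-3, gst-5 and cnc-4. Without L1 control array 1 they were clec-31, Y38E10A.14, che-2, jbts-14, ttll-11, tni-3 and gst-5, without 2 col-142 and ttll-11, without 3 che-2, ins-22 and cnc-4, and without 4 jbts-14 and grd-3. Without adult mutant array 1 they were grd-3 and tni-3, without 2 tni-3, and without 3 ttll-11 and tni-3. Without adult control array 1 all of these stayed but fbxb-85, and without 3 R102.2, che-2, jbts-14 and ins-22 did. Where they ended, the adjusted p lay between 0.0504 and 0.139. The interaction medians of the lists that differed were 0.357 for the IFT particle, 0.202 for the transition zone, 0.203 for other ciliary genes, 0.145 for male-specific genes, 0.249 for detoxification, -0.289 for moulting, -0.137 for muscle, -0.093 for the early embryo and -0.107 for the cell cycle; those of the male-specific, moulting, muscle and cell cycle lists each ended without single arrays named beside the result (adjusted p up to 0.181, 0.221, 0.374 and 0.208).

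The first pattern weighed was that ciliary genes fell at L1 and had no call in adults. Of the 22 genes, 10 passed a test of that difference and 12 did not, and choosing them for the L1 fall favours passing. A difference in scale between the stages is argued against as the whole cause, because the IFT particle list still differed after all arrays were quantile normalized together (camera adjusted p = 2.12e-07). That step rescales the deposited values and cannot undo the earlier processing, so separate normalization itself was not tested. RNA quality at L1 is argued against as the whole cause: with the Gapdh 3' minus 5' signal as a covariate the IFT particle list had an adjusted p = 7.61e-08 and a median of -0.23. With the covariate the medians of IFT motors (-0.229 against -0.185), the transition zone (-0.24 against -0.195) and the BBSome (-0.127 against -0.052) were larger in size, while that of other ciliary genes was smaller (-0.118 against -0.19). Only 14 of the 22 genes stayed lower, however, and the number of probe sets past the threshold was 95 with the covariate and 257 without it. The covariate moved with genotype, which costs precision, so a part of the L1 calls was not told from RNA quality. Swapped adult arrays are argued against by daf-19, whose lowest adult control array lay 0.43 above the highest adult mutant array. What stays open is that whole adults may carry too little ciliary signal to show a fall: the 22 genes ranked lower in adult controls than even in L1 mutants, by a median of -8.5 percentile points (95% interval -13 to -5.7), and 17 of the 22 did. That is less plain for ttll-4, ifta-1, che-3, xbx-9 and osm-5, which ranked at percentiles of 85.5, 56.2, 55.9, 54.5 and 52.5 in adult controls. A change in what DAF-19 controls with age stays open beside it, and neither the dilution by other adult tissue nor that change was told from the other. RNA quality also moved with stage, with a Gapdh 3' minus 5' signal of 3.16 to 4.12 at L1 and -0.54 to -0.36 in adults. A technical difference between the stages was not told from either.

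The second pattern was that fbxb, skr and early embryo genes lay lower in adult mutants. A single deciding array is argued against for the fbxb family, whose median lay between -0.232 and -0.167 with each adult array left out in turn. Its camera adjusted p was then at most 4.17e-16 at the preset correlation, although its count of called genes was not kept. Probe sets that match several family members are argued against as the cause, since plain fbxb probe sets alone gave a median of -0.17. Their camera adjusted p = 2.39e-18 used the preset correlation. Fewer embryos in the adult mutants may contribute and could not be told apart from an effect in the adults: of 15 early embryo genes above the adult median level, 60% were lower in the mutant, with an exact 95% interval of 32.3 to 83.7%. With an estimated correlation neither family passed (adjusted p = 0.0861 for both).

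The third pattern was that cuticle collagens lay lower in the mutant at both stages. At L1 the spread between arrays is argued against: the mean over col genes differed by -0.28 in the replicate pairs with an SD of 0.07, at an adjusted p = 0.00458 over all 165 families (limma), although the family did not pass camera with an estimated correlation (0.693). Of the other families that camera called at L1, che passed this paired test (adjusted p = 0.0011). Its called genes, che-2, che-3 and che-11, were ciliary genes already counted. The families pals (0.0875), osm (0.0875), srd (0.354), gcy (0.367) and gst (0.367) did not. Families without a camera call that passed it were hrg and dbd, both lower (0.0203 each), and pho, higher (0.0486). Swapping genotype within the 4 pairs gave an exact p = 0.125, which says nothing since 16 swaps can give no smaller one, and a permutation of all 8 arrays (p = 0.0286) ignores the pairs. RNA quality at L1 is argued against as the whole cause by the family's median. It was -0.275 with the Gapdh signal as a covariate and -0.266 without it. The camera adjusted p = 1.11e-19 of that fit decides little, since it used the preset correlation and an estimated one was not run there. Probe sets that match several family members are argued against as the cause, since plain probe sets alone gave a median of -0.24. Their camera adjusted p = 4.24e-18 also used the preset correlation. In adults the spread between arrays could not be told apart from an effect of genotype (exact permutation p = 0.2, where 0.1 is the smallest possible), and adult control array 1 had a col score of -0.06 against 0.13 and 0.25 in the other controls. A different phase of the moulting cycle at L1 may contribute and stays open: 2 of 28 moulting genes (7.1%) had an unadjusted p under 0.05 against 10.5% of all genes (Fisher's exact p = 0.763). An effect of daf-19 on the epidermis at L1 remains among the open explanations.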

How the results depend on the processing

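The replicate block within each stage, the test of the lists with plain probe sets and the pooled ciliary count were chosen after the data had been seen. The other alternatives were planned. Named genes kept direction and side of the threshold in 4970 comparisons with an alternative, lost a call in 245 and gained one in 106; lists did so in 2086, 59 and 49 and turned direction in 7. Of the named genes called, 32 of 58 at L1, 17 of 37 in adults and 16 of 16 in each stage contrast stayed past the threshold under every alternative run; of the 10 largest interaction differences, 5 each way, 9 did. The IFT particle and other ciliary lists passed at L1 and in the interaction under every alternative run, with adjusted p at most 0.0496 and 9.87e-06 at L1 and 0.0123 and 0.000383 in the interaction, or 0.0177 with an estimated correlation. The L1 count of 257 was 525 with a block within stage, which follows replicate pairs, 98 with only the compared groups, 156 with a floor and 402 at an unadjusted p with a 1.5-fold change. The adult count was 427, 549 and 498 with that block, the floor and that rule and 1996 with array weights, which gave adult control array 1 a weight of 0.52 and array 2 one of 5.03. The interaction gave 420 with that block, 905 with weights and 855 with that rule. The planned block gave 334, 265 and 260. Stage counts were 12277 and 12216 without dim probe sets, since fewer were tested. Genes lower at both stages numbered 7 with the planned block and with a trended, robust variance, 14 with the block within stage, 8 without dim probe sets, 0 with only the compared groups and 22 with weights; genes higher at both numbered 5 with the block within stage and 6 with weights. With 1 array left out, counts lay between 153 and 331 at L1, 103 and 765 in adults, 91 and 562 in the interaction and 2 and 13 for genes lower at both stages. At the same time, medians lay between -0.155 and 0.013 for the BBSome at L1, -0.003 and 0.162 for it in the interaction and 0.096 and 0.232 for IFT motors in the interaction. The IFT motors at L1 lost their call at -0.185 with the block within stage (adjusted p = 0.0558), -0.133 without dim probe sets (0.117), -0.064 with plain probe sets (0.685) and with an estimated correlation (0.124), and in the interaction passed at 0.141 after joint quantile normalization (0.0451). The BBSome passed at L1 at -0.062 (0.0463) and -0.057 (0.0495) after joint and per-stage quantile normalization and at -0.052 (0.0379) with a trended variance. The transition zone turned to 0.164 (0.34) at L1 and -0.005 (0.861) in the interaction without dim probe sets, which left 2 of 14 genes; its interaction call ended at 0.193 (0.052) with plain probe sets and at 0.219 with an estimated correlation, which took its L1 value to 0.0602. In adults, lists turned to 0.01 (0.401) for glia without dim probe sets, -0.132 for FMRFamide-like and -0.125 for other neuropeptides without adult control array 1 (up to 0.062 and 0.183 without 1 array), 0.005 for muscle without adult control array 3 (down to -0.145 without 1 array) and -0.017 for innate immunity with plain probe sets. With plain probe sets alone, calls ended for identity regulators, glia, muscle and germline in adults (0.0898 to 0.13), for cell cycle and germline at L1 (0.092 and 0.102) and for early embryo, cell cycle, moulting, muscle and male-specific genes in the interaction (0.0748 to 0.195), and innate immunity passed (0.0205 at L1, 0.0316 in adults, 0.000582 in the interaction). With the mean of all probe sets, calls ended for the cell cycle at L1 and in the interaction (0.0704 for both) and for muscle (0.0917) and male-specific genes (0.0513) in the interaction, and without dim probe sets for muscle there (0.0654). Adult detoxification passed after joint quantile normalization (0.0205), without dim probe sets (0.0246), with only the adult groups (0.0147) and with the block within stage (0.0492), as did intestine with the planned block (0.049) and with the mean (0.0491) and sugars after joint normalization (0.0471). Ribosomal proteins passed after joint and per-stage normalization at L1 (0.0318 and 0.00936) and in the interaction (0.0451 and 0.0192), glia in the interaction with both (0.0451 and 0.0336) and with a trended variance (0.0454), and male-specific genes at L1 without dim probe sets (0.0182). Except where fewer probe sets or arrays explain a change, the cause was not tested. Adult replicate numbers did not pair all arrays: correlations were 0.04 to 0.44 for like and -0.34 to 0.33 for unlike numbers. Mutant array 1 and control array 1 correlated at 0.44, and at -0.34 to -0.18 with the other arrays of the opposite genotype. Numbers 2 and 3 gave 0.11 and 0.04. Whether the arrays numbered 1 share a structure was not tested. How far signal over background limits the adult ciliary genes was not measured; their control signals ranked at a median percentile of 28.2. Other X-box motifs, promoter lengths and values on the linear scale were not run.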

Other observations

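The tests in this part, the other splits of the arrays and the calls near daf-19, were planned before the data were examined; the comparison of splits that part the replicate pairs and the genes named here were chosen after the result was seen.

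Refitting other splits of the same arrays gave, at L1, 2 of 35 splits with as many probe sets as the real 257, so chance could not be excluded by that count. The other was the split of replicates 1 and 4 against 2 and 3 of both genotypes, with 593 probe sets, which points to a structure of the samples that follows the replicate numbers. Among the 8 splits that part every replicate pair, as the real one does, the highest other count was 0, and with the pairs as a block the real count was 525. In adults, 1 of 10 splits, the real one with 71 higher and 160 lower, gave as many, with 1 as the highest other; 10 splits are too few for a share under 0.05. For the interaction, 1 of 100 splits gave as many as the real 206, with 84 as the highest other. These splits shuffled the L1 arrays without regard to the replicate pairs, all of which the real split parts, so they do not exclude chance. For the stage contrasts, 1 of 35 splits gave as many as the real 20312 in controls (highest other 17707) and 1 of 35 as many as 20300 in mutants (17448), so chance is excluded there.

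Variation linked to the daf-19 mutation might add calls among its neighbours on the chromosome. Of the 200 genes nearest to daf-19, 1 was called at L1, pho-11, which is 0.5% against 1.22% of other genes (Fisher's exact p = 0.737), and 2 in adults, C07E3.9 and clec-61, 1% against 1.06% (Fisher's exact p = 1). So few calls leave the explanation open for those genes, since both differences lie within sampling error.

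Control probe sets of the array, left out of the comparisons, gave 0 past the threshold by limma in either genotype contrast, with 3 at L1 and 1 in adults at an unadjusted p under 0.05. The median, mean and test of a list differed in sign in 0 of the 24 list tests past the threshold and in 15 of the others: in adults the lists of innate immunity, FMRFamide-like peptides, insulin-like peptides, yolk proteins, lipids and ribosomal proteins, at L1 those of insulin-like peptides, intestine, heat shock, immunity and DAF-16 targets, and in the interaction those of sensory transduction, germline, sperm and heat shock.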
